A study of Mus musculus with 19 samples.

How the data were processed

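The study profiled cortex of E14.5 mouse embryos by RNA sequencing, in wildtype controls and in mutants with an active Smoothened (GFAP::Cre; SmoM2). RNA was taken from dissected cortex with the RNeasy Micro Kit, and libraries were made with the TruSeq Stranded Total RNA Kit, per the labels. The deposited table holds TPM (transcript levels scaled to a fixed total per library) computed by the authors, with 1 column per library and 47643 gene symbols, on genome build mm10. Each column sums to 1000000, so the values are scaled by gene length and library total and the sequencing depth is unknown; no counting error can be given. The aligner, the quantifier, the annotation release and the use of strand are not given in the sources used here. In the table, 24353 genes lay above 0 in at least 1 library and 244 symbols carried a numeric suffix that separates genes of the same name.

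Libraries were placed into groups by their titles: 6 control dorsal (numbers 1 to 6), 4 mutant dorsal, 5 control medial (numbers 2 to 6) and 4 mutant medial libraries. The labels do not say that libraries of a group come from separate embryos, so p-values measure the spread between libraries, which may be technical. Whether the title numbers pair libraries was checked on the deviations from the group means over the tested genes. Dorsal and medial libraries of the same genotype and number correlated in all 9 pairs (r from 0.549 to 0.795), and 18 of 18 libraries with a partner were closest to their own number. The numbers were therefore treated as embryos within a genotype, a pairing that comes from the data. Across genotypes, libraries of the same region and number had r from -0.436 to 0.138 in 7 pairs, so the number does not pair controls with mutants. Embryo sex was read from Xist and Ddx3y.

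Genes with at least 1 TPM in at least 4 libraries were tested (13520 genes), on log2(TPM + 1). Linear models with 1 mean per group over all 19 libraries were fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with empirical Bayes moderation using the mean-variance trend and robust settings. This main fit had no term for the embryo, and blocks by embryo were among the alternatives. Adjusted p-values follow Benjamini and Hochberg within each comparison, with a threshold of 0.05. The 5 comparisons were mutant against control in dorsal cortex, mutant against control in medial cortex, the difference between these effects (medial minus dorsal), medial against dorsal control cortex, and medial against dorsal mutant cortex. Values are printed as mean ± SD of TPM over the libraries of a group, or as log2 change ± standard error from limma. The libraries of 2 groups were said not to overlap where each library of 1 group lay beyond each library of the other; between regions the count was also set against splits that exchange libraries only within embryos, added after the data were seen. The log2 changes of both regions were compared by Pearson's r across genes, with 100 shuffles of genotype over the embryos, in which the genes called in both regions were counted as well, a count added after the data were seen.

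A total of 36 gene lists (pathways, cell types, regions, sample quality) were written before the data were examined, as were the tests, the filter, the rule for naming genes and the alternatives below except those said to be added. They hold 595 measured members that passed the expression filter in this tissue, of which 57 are in more than 1 list. Each list was tested against the other genes with camera in limma at a preset correlation of 0.01 and, as an alternative, with the correlation estimated. Against the direction of camera, the median of a list had the other sign for 13 lists dorsally, 10 medially and 7 in the difference between regions, and the mean for 10, 9 and 7; for each regional comparison at most 1 list did so. Among lists that passed, this was so only for the Hedgehog targets dorsally (median). Members past the test were counted with p adjusted over all genes and adjusted over the list alone.

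Genes are named by a fixed rule: per comparison, the 10 largest increases and 10 largest decreases among genes past the threshold whose groups do not overlap (for the difference between regions, the threshold only). The ranking leaves out predicted and clone names, small RNA, mitochondrial and pseudogene names and 6 sex-linked genes. Up to 4 members per list were named by adjusted p, and Smo, Gli1, Ptch1, Hhip, Gli2, Gli3, Cdk6, Cdk4, Ccnd1, Ccnd2, Eomes, Hopx, Pax6, Sox2, Shh and Olig2 always. Some genes that this rule names are not reported here. Genes named after their values were seen are said to be so. Coordinates are 1-based positions of whole genes from GENCODE M21 on GRCm38 (the same assembly as mm10), read with Python 3.11.15; 13056 of 13520 tested symbols (96.6%) matched 1 position there. Plots were drawn with matplotlib 3.10.9.

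The test was tried on simulated data, drawn around each gene's mean with its SD within groups and independently between genes, in which a small part of the 13520 genes was shifted. Of the genes shifted by a log2 change of 1, it recovered 89.6% (dorsal), 92.5% (medial), 89.6% (difference between regions), 92.5% (control regions) and 85.1% (mutant regions), and of those shifted by 0.5 between 53.7% and 77.6%. Among 13320 unshifted genes it called at most 12, and of 36 lists without change camera called 0; correlation between genes was not simulated.

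The alternatives were a pseudocount of 0.1 or 5, no filter, a filter at 5 TPM, quantile normalization, median-ratio rescaling, rescaling without mitochondrial genes and the 50 highest genes, a fit on the libraries of a comparison alone, array weights, moderation without trend and robust settings, the title number as a fixed block, the embryo as a random block, and leaving out each of the 19 libraries in turn. Added after seeing the data were embryo sex as a covariate, male libraries alone, the main axis of variation between embryos as a covariate or as 2 subsets, and each embryo as a fixed block. Leaving out libraries for the gene lists was added then too. Other splits of the same libraries into groups of the same sizes were drawn, 100 where more exist. Added after the data were seen were splits with each embryo as a block for the difference between regions. Splits that part each embryo's pair of libraries were added then as well, for the regional comparisons. Tools for counts were not used because the table holds no counts. Reads, isoforms and the SmoM2 sequence were not analysed here.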

Results

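Gene expression was measured by RNA sequencing of cortex from E14.5 mouse embryos (E, embryonic day). The mutants carried GFAP::Cre; SmoM2, in which Cre recombinase switches on SmoM2, a form of Smoothened that is always active; Smoothened is the membrane protein that passes on the Hedgehog signal. The controls were wildtype. The 19 libraries formed 4 groups: 6 control dorsal, 4 mutant dorsal, 5 control medial and 4 mutant medial libraries. The tissue field of the sample labels reads dorsal or medial cortex, while the protocol text names medial or lateral pieces. Values were in TPM, transcript levels scaled to a fixed total of 1000000 per library, for 47643 gene symbols, so the sequencing depth is unknown. Between 17357 and 18670 genes lay above 0 per library, and Pearson's r across tested genes between replicates of a group ran from 0.975 to 0.993. Xist and Ddx3y, genes of the X and Y chromosomes that tell the sexes apart, marked control embryos 2, 3 and 4 as female. Control embryos 1, 5 and 6 and all 4 mutant embryos were male by the same genes, so sex is not balanced between the genotypes.

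The first comparison asks what the active Smoothened changed in dorsal cortex (4 mutant against 6 control libraries; log2 changes in TPM + 1 with standard error, SE, from limma). Gli1, the transcription factor gene that Hedgehog signalling switches on (chromosome 10, 127329882 to 127341974, GRCm38), went from 0.586 ± 0.268 to 35 ± 5.44 TPM (mean ± SD, n = 6 and 4), a log2 change of 4.51 ± 0.16. Ptch1, which encodes the Hedgehog receptor (chromosome 13, 63508328 to 63573598), rose by 3.18 ± 0.11 from 5.98 ± 0.676 to 62.6 ± 10.2 TPM. Hhip, whose product binds Hedgehog ligands (chromosome 8, 79965851 to 80058006), rose by 4.79 ± 0.18. Fgf15, a growth factor gene of progenitors (chromosome 7, 144896531 to 144900953), went from 0.416 ± 0.172 to 66.4 ± 12.8 TPM. For each of these 4 genes all 4 mutant libraries lay above all 6 control libraries, with adjusted p between 4.58e-13 for Ptch1 and Fgf15 and 1.38e-12 for Hhip. Smo itself rose by 0.61 ± 0.09 (adjusted p = 4.12e-05); a gene-level value does not separate the SmoM2 transcript from the native one. Gli2, which encodes an activator of the pathway, rose by 0.44 ± 0.12 (adjusted p = 0.00938; 0.0512 without mutant dorsal library 3). Gli3, which encodes mainly a repressor, fell by 0.36 ± 0.14 (adjusted p = 0.0424), and 6 of the 19 fits that each left out 1 library lost that call (control dorsal 1, 3 and 5 and mutant dorsal 1, 2 and 4; adjusted p up to 0.152). Shh, the ligand gene, stayed below the expression filter, with means of 0.0395 TPM in control and 0.0230 TPM in mutant dorsal libraries. Of the 13 Hedgehog target genes measured, 5 rose and 4 fell (5 and 5 adjusted over the list alone), with a median log2 change of -0.08 and a mean of 1.03. The list passed camera in the upward direction, against the sign of its median (adjusted p = 0.00836), and did not with the correlation between genes estimated (adjusted p = 0.248 with an estimated correlation).

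Cell cycle genes rose across their lists in dorsal cortex. Cdk6, the cyclin-dependent kinase gene named in the study's title (chromosome 5, 3341485 to 3531008), went from 21.1 ± 4.03 to 61.9 ± 11.5 TPM, a log2 change of 1.51 ± 0.19 (adjusted p = 1.18e-05). Its partner cyclins rose too, Ccnd1 (chromosome 7, 144929931 to 144939925) by 1.41 ± 0.15 and Ccnd2 by 0.92 ± 0.10, and for all 3 genes the mutant libraries lay above the control libraries without overlap. Cdk4, the sister kinase of Cdk6, rose by 0.12 ± 0.04 (adjusted p = 0.0153; 0.0694 without mutant dorsal library 3). E2f1, a transcription factor gene of S-phase entry, rose by 1.23 ± 0.10, and Cdkn1c, which encodes an inhibitor of cyclin-dependent kinases, fell by 0.71 ± 0.07. All 43 of 43 S-phase genes rose (43 adjusted over the list alone), with a median of 0.80. Of 51 G2/M genes, 46 rose (47 adjusted over the list alone), with a median of 0.67. Of 24 G1 cyclins, kinases, inhibitors and E2Fs, 16 rose and 3 fell (16 and 3 adjusted over the list alone). Of 23 replication-dependent histone genes, 22 rose (22 adjusted over the list alone), and histone genes took 6.46% of all TPM in control and 11.2% in mutant dorsal libraries. Histone genes share reads with near-identical copies, so their single values are uncertain. These 4 lists passed camera, with adjusted p of 3.60e-52 for S phase, 1.00e-46 for G2/M, 1.17e-10 for G1 and 7.76e-27 for histones, and each also passed with an estimated correlation (adjusted p = 0.0401).

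Genes of ventral forebrain progenitors were higher in mutant dorsal cortex. Olig2, a transcription factor gene of ventral progenitors and oligodendrocyte precursors (chromosome 16, 91225457 to 91228677), went from 1.27 ± 0.247 to 15.9 ± 5.97 TPM, a log2 change of 2.82 ± 0.29 (adjusted p = 8.15e-07). Gsx2, which patterns the lateral ganglionic eminence, rose by 1.48 ± 0.28 (adjusted p = 0.000547). Of the 8 ventral telencephalic progenitor genes measured, 3 rose (5 adjusted over the list alone) and the list passed camera (adjusted p = 0.000668, and 0.0401 with an estimated correlation). Deep-layer neuron genes moved down: 14 of 23 fell (17 adjusted over the list alone, 11 after median-ratio rescaling), with a median -0.42 relative to all genes (camera adjusted p = 0.00554; adjusted p = 0.263 with an estimated correlation). Nxph4, a neurexophilin gene of deep layers, fell by 1.22 ± 0.11. Unc5d, a netrin receptor gene of upper-layer neurons, fell by 1.20 ± 0.11. Of 24 pan-neuronal genes, 14 fell (16 adjusted over the list alone); after median-ratio rescaling 6 fell and 1 rose, and the list did not pass camera (adjusted p = 0.0678). Interneuron genes did not pass as a list either, with 6 of 24 lower (6 adjusted over the list alone; camera adjusted p = 0.152). Both neuronal lists passed camera after quantile normalization; over all alternatives the adjusted p ran from 0.00376 to 0.938 for the pan-neuronal and from 0.0404 to 0.938 for the interneuron genes. The pan-neuronal list also passed without control dorsal library 1 (0.0287), mutant dorsal 2 (0.0102) or mutant dorsal 4 (0.0306).

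The largest single rise in dorsal cortex was that of Prm1, a sperm chromatin gene (chromosome 16, 10796326 to 10805839), from 0.166 ± 0.266 to 232 ± 114 TPM; Prm2 reached at most 0.0945 TPM in any mutant library. Behind Prm1, Fgf15, Hhip, Gli1, Ptch1 and Olig2, the 10 largest rises held Dio3, a thyroid hormone deiodinase gene (3.45 ± 0.35), Crh, the corticotropin-releasing hormone gene (3.36 ± 0.75), Cpxm2 (2.86 ± 0.19) and Synm, an intermediate filament gene (2.69 ± 0.14). The largest falls were those of Dct, a melanin synthesis enzyme gene (-3.04 ± 0.46), and Loxl1, which encodes a lysyl oxidase that links elastin (-2.17 ± 0.38). Ly6g6e, Kif26b, Cemip, Nfatc4, Cldn3, Hs3st1, Pcdh7 and the cell adhesion gene Alcam (-1.38 ± 0.20) completed the 10 largest falls. All 20 genes have adjusted p below 0.05 in limma and no overlap between the 2 groups of libraries. Over 13520 genes tested, 5070 passed, 1343 higher and 3727 lower in the mutants, of which 88 and 48 changed at least 2-fold. The split by direction follows the scaling: 2112 genes were higher and 1921 lower after median-ratio rescaling, and 1959 and 2173 after quantile normalization. The median change of all genes was -0.10 dorsally and -0.11 medially as deposited, and quantile normalization moved the medial one by 0.11. The libraries did not overlap for 3356 genes, 24.8% of those tested where chance gives 0.952%. Camera called 7 of 36 lists, and 59 of 100 splits of the same 10 libraries called as many.

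**Figure D1:**
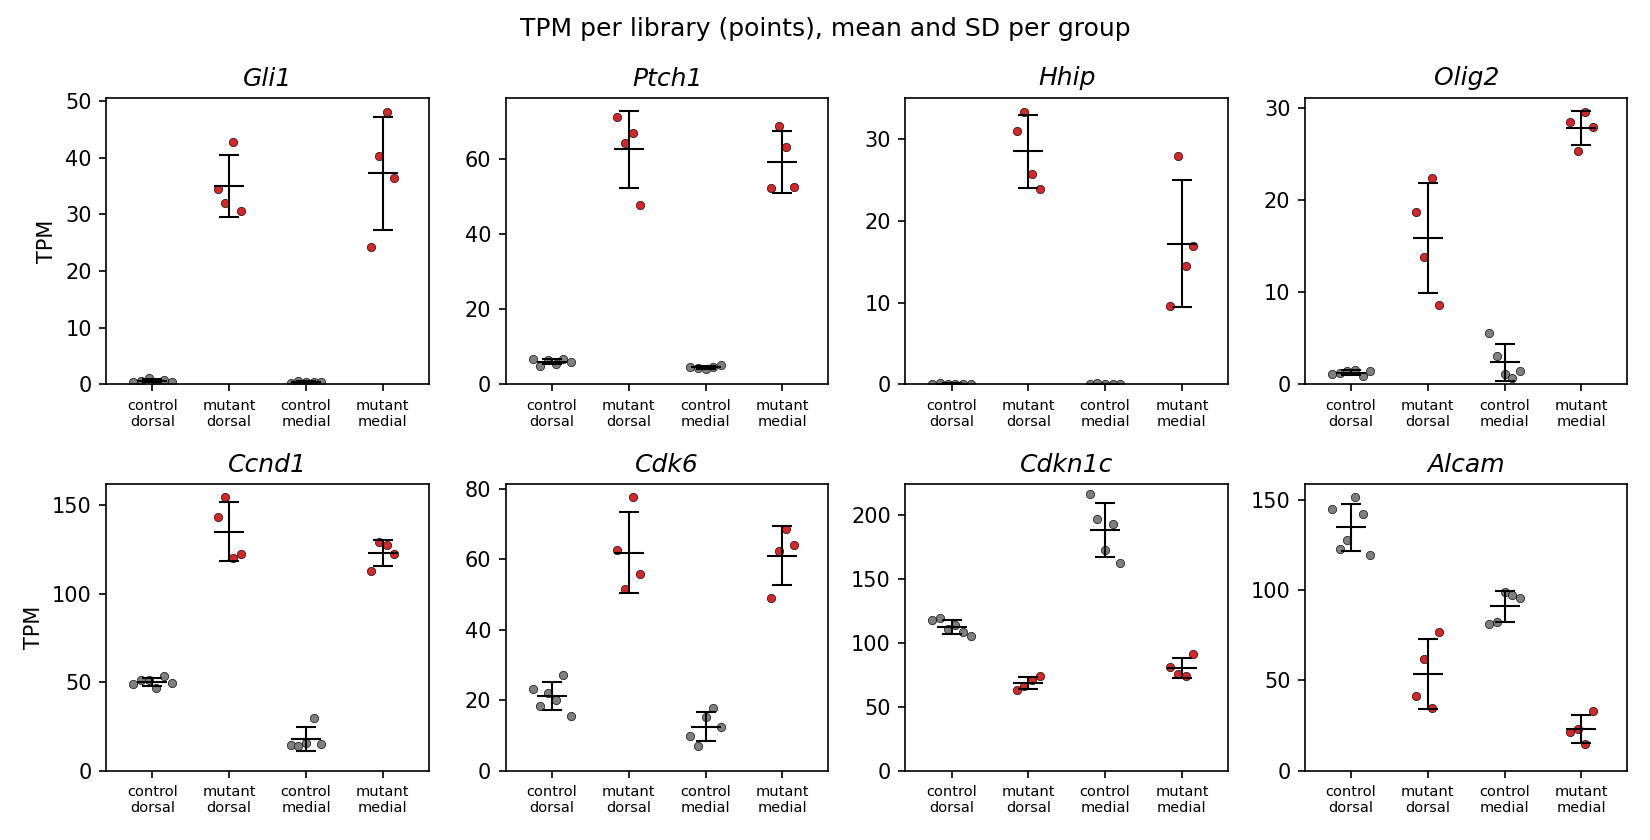
TPM (vertical axis, linear, from 0) of 8 genes in the 19 libraries (points) of the 4 groups on the horizontal axis, with mean and SD per group (bars). Gli1, Ptch1, Hhip, Olig2, Ccnd1 and Cdk6 were higher and Cdkn1c and Alcam lower in the mutants of both regions.

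The same question was asked of medial cortex (4 mutant against 5 control libraries). Gli1 went from 0.398 ± 0.135 to 37.2 ± 9.94 TPM, a log2 change of 4.74 ± 0.16 (adjusted p = 4.59e-13), Ptch1 rose by 3.45 ± 0.11 and Hhip by 4.03 ± 0.19. Ccnd1 went from 17.7 ± 6.70 to 123 ± 7.29 TPM, a log2 change of 2.79 ± 0.15, and Cdk6 from 12.5 ± 4.23 to 61.1 ± 8.42 TPM, a log2 change of 2.25 ± 0.20 (adjusted p = 3.24e-07). For these 5 genes no mutant library overlapped a control library. Ccnd2 rose by 0.56 ± 0.10, Smo by 0.47 ± 0.09 and Gli2 by 0.47 ± 0.13, while Gli3 (-0.14 ± 0.14, adjusted p = 0.453) and Cdk4 (0.06 ± 0.04, adjusted p = 0.218) did not pass. Cdk4 did pass limma medially under at least 1 processing alternative (lowest adjusted p = 0.0177), though in no fit without 1 library, so its absence medially depends on the processing. Cdkn1c fell by 1.21 ± 0.08. Of 13 Hedgehog target genes, 6 rose and 3 fell (6 and 3 adjusted over the list alone), with a median of 0.03 (camera adjusted p = 4.28e-05). All 43 S-phase genes (43 adjusted over the list alone), 45 of 51 G2/M genes (46 adjusted over the list alone) and 21 of 23 histone genes (22 adjusted over the list alone) rose. Of 24 G1 genes, 14 rose and 2 fell (14 and 3 adjusted over the list alone). These 4 cell cycle and histone lists passed camera with adjusted p from 9.37e-48 for S phase to 1.75e-08 for G1, and none of these 5 lists did with an estimated correlation (adjusted p = 0.0847 with an estimated correlation for each).

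Olig2 rose by 3.27 ± 0.30 in medial cortex, from 2.38 ± 1.98 to 27.8 ± 1.80 TPM. The ventral progenitor list moved both ways, with 2 members higher and 2 lower, Dlx1 among the latter (without mutant medial library 3 its adjusted p was 0.0877; 3 and 2 adjusted over the list alone). It passed camera upward (adjusted p = 0.0278; adjusted p = 0.175 with an estimated correlation) but not after quantile normalization, with the title number as a fixed block or without 1 of 6 libraries (mutant dorsal 1, 2 and 3, control medial 5 and mutant medial 1 and 2), with adjusted p over all alternatives from 0.00268 to 0.175. Interneuron genes fell, 17 of 24 (18 adjusted over the list alone, 15 after median-ratio rescaling), with a median -0.56 relative to all genes (camera adjusted p = 0.00205; adjusted p = 0.518 with an estimated correlation). Sp8, a transcription factor gene of interneurons and progenitors, fell by 0.98 ± 0.18. Of 24 pan-neuronal genes, 16 fell (18 adjusted over the list alone, 13 with 1 higher after median-ratio rescaling), with camera adjusted p = 0.00235 (adjusted p = 0.662 with an estimated correlation). Gap43, which encodes a growth cone protein, fell by 0.59 ± 0.09. Of 23 deep-layer genes, 14 fell (16 adjusted over the list alone), with camera adjusted p = 0.00947 (adjusted p = 0.307 with an estimated correlation). The endothelial list passed camera upward (adjusted p = 0.0178; adjusted p = 0.623 with an estimated correlation) with 1 of 18 members past the test, Apln (0.53 ± 0.11), a ligand gene of vessel tips (1 adjusted over the list alone); without mutant medial library 3 the list's adjusted p was 0.0833. Pericyte, erythroid and microglia lists did not pass in either region.

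The 10 largest medial rises were those of Prm1 (0.182 ± 0.208 to 307 ± 167 TPM), Fgf15, Gli1, Hhip, Crh, Ptch1, Olig2, Ccnd1, Cacng5, an AMPA receptor subunit gene (3.04 ± 0.19), and Entpd2, which encodes an enzyme that splits extracellular ATP (2.71 ± 0.27). The largest falls were those of Dct (-2.21 ± 0.48), Ly6g6e, Dio2, a deiodinase gene that activates thyroid hormone (-2.0 ± 0.28), Alcam (-2.0 ± 0.20), Nfatc4, Sstr1, Dusp26, Cemip, Prph and Kif26b. All 20 have adjusted p below 0.05 in limma without overlap between the libraries. Of 13520 genes, 5357 passed, 1276 higher and 4081 lower, with 85 and 140 at least 2-fold. Median-ratio rescaling gave 2183 higher and 2258 lower, quantile normalization 2164 and 2275. The libraries did not overlap for 4105 genes, 30.4% where chance gives 1.59%. Camera called 10 of 36 lists, as many as did 62 of 100 splits of the 9 libraries, and 0 with an estimated correlation (7 at an unadjusted p under 0.05).

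As deposited, progenitor lists moved in both directions in both regions. The median of all genes was -0.10 dorsally and -0.11 medially on this scale, so the balance of these lists and calls near the threshold may depend on the scaling. Sox2, a stem cell transcription factor gene, rose by 0.40 ± 0.08 dorsally and 0.45 ± 0.08 medially (adjusted p = 0.00100 and 0.000487), and Sox1 by 0.72 ± 0.11 and 1.42 ± 0.11. Pax6, a gene of cortical radial glia, rose medially (0.28 ± 0.09, adjusted p = 0.0226) and did not pass dorsally (0.16 ± 0.09, adjusted p = 0.172). The medial call was lost without control medial library 4 (0.0515) or mutant medial 3 (0.0935), and the dorsal one was gained without mutant dorsal 2 (0.0365). Aldoc, a glycolysis gene of radial glia, fell by 1.08 ± 0.11 and 1.34 ± 0.11. Of 24 radial glia markers, 8 rose and 9 fell (9 and 9 adjusted over the list alone) dorsally, and 6 rose and 6 fell (7 and 7 adjusted over the list alone) medially. Of 19 outer radial glia markers, 3 rose and 4 fell (3 and 5 adjusted over the list alone) dorsally, and 2 rose and 7 fell (2 and 7 adjusted over the list alone) medially. Hopx, the marker of outer radial glia, did not pass in either region (-0.83 ± 0.32, adjusted p = 0.0503, and -0.35 ± 0.33, adjusted p = 0.435), although 6 of the 19 fits without 1 library gained the dorsal call (control dorsal 3, mutant dorsal 3, control medial 2 and 5 and mutant medial 1 and 2; lowest adjusted p = 0.0290). Moxd1, another such marker, rose by 0.72 ± 0.21 dorsally (adjusted p = 0.0122; 0.0570 without mutant dorsal 3) and by 1.94 ± 0.22 medially, and the integrin gene Itgb5 rose by 0.92 ± 0.14 dorsally and 0.62 ± 0.14 medially. Eomes, the gene of intermediate progenitors, rose dorsally (0.26 ± 0.09, adjusted p = 0.0231) and did not pass medially (0.20 ± 0.09, adjusted p = 0.0780). Its dorsal call was lost without control dorsal 4 (0.0503), mutant dorsal 1 (0.0901) or mutant dorsal 3 (0.122), and the medial one was gained without mutant dorsal 2, mutant dorsal 3 or mutant medial 1 (0.0424, 0.0431 and 0.0356). Of 23 intermediate progenitor markers, 4 rose and 5 fell (4 and 5 adjusted over the list alone) dorsally, and 3 rose and 5 fell (3 and 5 adjusted over the list alone) medially. None of these 3 lists passed camera in either region (adjusted p from 0.309 to 0.920).

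Among signalling lists, the 13 FGF and ERK target genes had more members lower than higher: dorsally 1 rose and 5 fell (1 and 6 adjusted over the list alone), and medially 1 rose and 9 fell (1 and 9 adjusted over the list alone). Etv5, a transcription factor gene switched on by FGF, fell by 0.84 ± 0.22 and 1.18 ± 0.23, and the phosphatase gene Dusp4 by 0.93 ± 0.18 and 1.07 ± 0.19. The list did not pass camera dorsally or medially (adjusted p = 0.409 and 0.123) but passed medially after quantile normalization (medial adjusted p over all alternatives from 0.0390 to 0.656). Of 20 Notch genes, 3 rose and 6 fell (3 and 8 adjusted over the list alone) dorsally, and 2 rose and 8 fell (2 and 9 adjusted over the list alone) medially; the ligand gene Jag1 rose by 0.87 ± 0.11 and 0.71 ± 0.11. Of 12 BMP target genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone) dorsally, and 1 rose and 6 fell (1 and 8 adjusted over the list alone) medially, with the BMP antagonist gene Nog lower in both (-0.53 ± 0.09 and -0.62 ± 0.09). Of 12 Wnt target genes, 1 rose, Ccnd1, and 2 fell dorsally, and 1 rose and 5 fell medially. Of 23 Hedgehog pathway components, 3 rose and 5 fell dorsally, and 4 rose and 5 fell medially. Cdon, a co-receptor gene of the pathway, fell by 0.62 ± 0.07 and 0.66 ± 0.07. For the Wnt and pathway component lists the counts adjusted over the list alone were the same in both regions. Of 18 p53 targets, 3 rose and 4 fell dorsally, and 2 and 2 medially. Of 19 hypoxia genes, 3 rose and 4 fell dorsally, and 2 and 5 medially. Of 27 matrix and adhesion genes, 2 rose and 7 fell dorsally, and 2 and 6 medially. Adjusted over the list alone, these 3 lists gave the same counts. As deposited, most calls over all genes were lower, so the balance of these lists depends on the scaling. After median-ratio rescaling, higher and lower members were 1 and 3 dorsally and 1 and 8 medially for FGF targets, 3 and 5, and 2 and 6, for Notch genes, and 1 and 5 in both regions for BMP targets. The balance turned to more higher members dorsally for pathway components (6 and 4) and hypoxia genes (4 and 2) and in both regions for p53 targets (4 and 2 in each).

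The hem, Cajal-Retzius, pallium, upper-layer, oligodendrocyte precursor, striatal and ciliated cell lists did not pass camera in either region. Medially, 13 of 28 cortical hem and medial pallium genes fell and 2 rose (14 and 2 adjusted over the list alone; camera adjusted p = 0.0912). The list passed after quantile normalization, with the title number as a fixed block and without control medial 4, control medial 5 or mutant medial 1, with adjusted p over all alternatives from 0.000677 to 0.882. Dmrt3, a transcription factor gene of the medial pallium, fell by 1.54 ± 0.33, and dorsally 2 rose and 8 fell (2 and 8 adjusted over the list alone). Of 14 Cajal-Retzius cell genes, 1 fell dorsally and 8 medially (the same adjusted over the list alone), Reln, which encodes the secreted guidance protein of these cells, by 0.92 ± 0.20 medially. Of 17 lateral and dorsal pallium genes, 4 rose and 6 fell (5 and 6 adjusted over the list alone) dorsally, and 6 rose and 5 fell (7 and 6 adjusted over the list alone) medially; the list passed medially with embryo sex as a covariate, with male libraries alone and without control medial 2, control medial 4 or mutant medial 1 (adjusted p over all alternatives from 0.0377 to 0.221). Dbx1, a transcription factor gene of the ventral pallium, rose by 2.17 ± 0.26 and 2.68 ± 0.27. Of 18 upper-layer genes, 6 fell dorsally, and 5 fell and 1 rose medially. Of 11 oligodendrocyte precursor genes, 2 rose, Olig2 and the growth factor receptor gene Egfr, and 1 fell in each region; the list passed dorsally with male libraries alone (0.0462) and without mutant dorsal 3 (0.0310), within a range over all alternatives of 0.0310 to 0.227. Of 7 striatal and thalamic genes, 1 fell dorsally and 2 medially. Of 5 ciliated cell genes, 2 fell and 1 rose dorsally, and 2 fell medially. Adjusted over the list alone, these 4 lists gave the same counts.

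The next lists cover cells outside the neural lineage and sample quality. Of 15 meningeal genes, 2 fell dorsally and 4 medially (2 and 3 adjusted over the list alone). Of 11 pericyte genes, 4 and 2 fell (the same adjusted over the list alone), among them Notch3 (-0.70 ± 0.14 and -0.56 ± 0.15). Of 15 microglia genes, 6 and 1 fell (7 and 0 adjusted over the list alone). Of 18 endothelial genes, 2 rose and 1 fell (2 and 0 adjusted over the list alone) dorsally. Of 11 erythroid genes, 1 fell dorsally and 0 medially (0 and 0 adjusted over the list alone; 0 at an unadjusted p under 0.05 in limma medially). Of 11 choroid plexus genes, 0 passed dorsally and 1 fell medially (0 and 0 adjusted over the list alone; 0 higher and 0 lower at an unadjusted p under 0.05 in limma dorsally). Of 16 immediate early and heat shock genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone) dorsally, and 3 rose and 3 fell (2 and 3 adjusted over the list alone) medially. No mitochondrially encoded gene passed limma (13 measured; 0 lower dorsally and 1 medially at an unadjusted p under 0.05). None of the 5 sex-linked genes passed either (0 and 1 at an unadjusted p under 0.05); the controls held both sexes and all mutants were male.

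**Figure D2:**
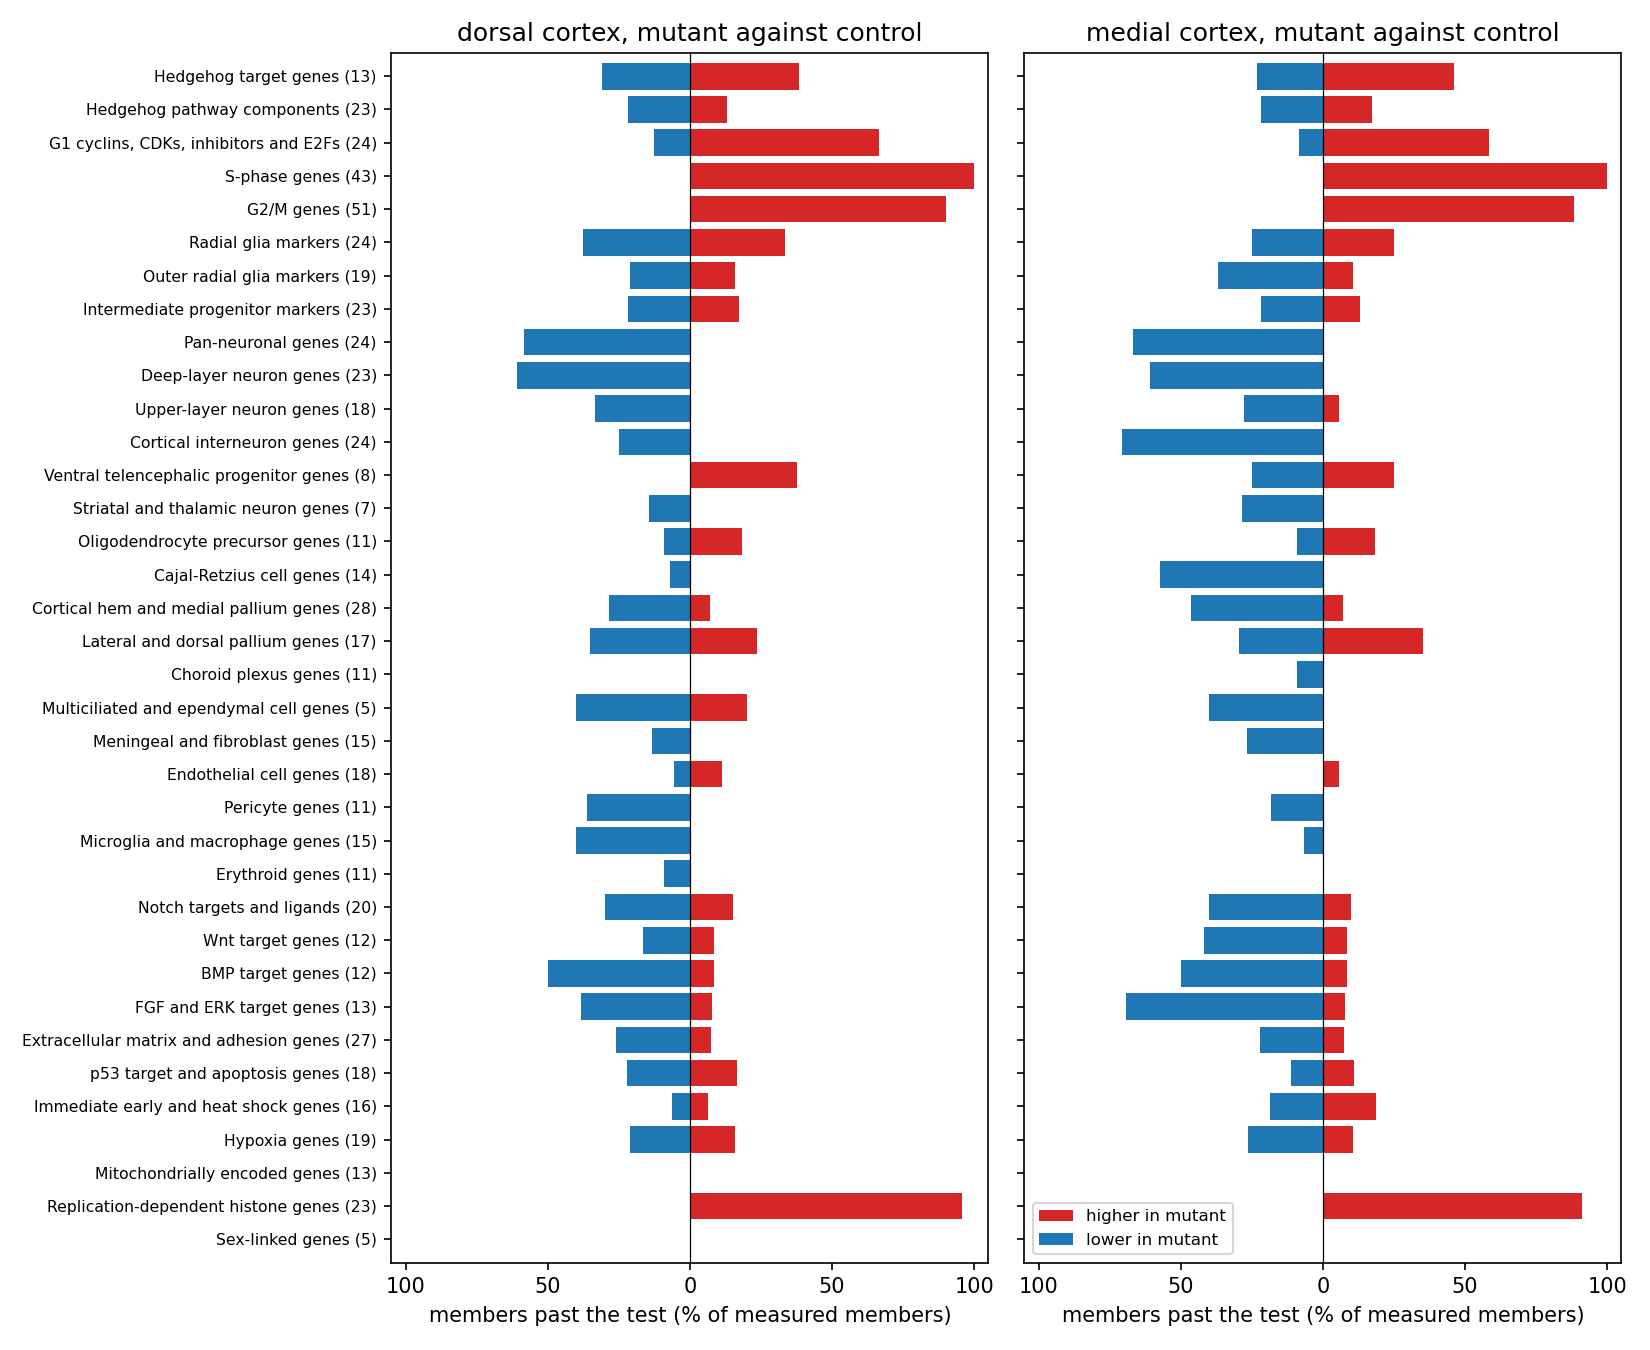
Share of each list's measured members (number in parentheses) with adjusted p below 0.05 in limma, higher (to the right) or lower (to the left) in the mutants, in dorsal (left panel) and medial cortex (right panel). All 43 S-phase genes were higher in both regions.

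The second question is whether the mutant effect differed between medial and dorsal cortex. The main fit has no term for the embryo, so the spread between embryos stays in this comparison, although most libraries pair by embryo. In that fit Ccnd1, the cyclin D1 gene, was the only gene of 13520 past limma's test of the difference (1 gene, with 451 at an unadjusted p under 0.05). Its mutant effect was 1.38 ± 0.21 larger medially (adjusted p = 0.0464): it stood at 50.1 TPM in dorsal and 17.7 TPM in medial controls, and at 135 and 123 TPM in the mutants. Of the 19 fits that each left out 1 library, 2 kept this call, without control dorsal library 1 (adjusted p = 0.0347) and without control medial library 5 (1.58, adjusted p = 7.18e-08); leaving out any other library lost it. Over all 37 alternatives the adjusted p ran from 7.18e-08 to 1.00 and the difference stayed above 0 (0.81 to 1.58); the 0.81 comes from a subset of the embryos (split A: control embryos 1 and 5 and mutant embryos 3 and 4) whose only medial control is library 5. Cdk6 differed in the same direction without passing (0.74 ± 0.28, adjusted p = 1.00), as did Gli1 (0.23 ± 0.23) and Ptch1 (0.27 ± 0.15). With the embryo as a random block, 49 genes passed, 24 higher and 25 lower, Ccnd1 (adjusted p = 0.00175) and Cdkn1c among them. The Cdkn1c difference was -0.50 ± 0.11, with adjusted p = 0.302 without the block, 0.00693 with it and 0.00693 to 1.00 over all alternatives. Of the other genes named in this text, the random block also called the difference for Sox1, Cacng5, Moxd1, Prokr1 and Lypd1 (medial minus dorsal above 0) and for Prph and Adamts19 (below 0, with the larger fall medially), and each embryo as a fixed block for Sox1, Cacng5, Prokr1, Lypd1 and Alcam; for Sox1 the adjusted p ran from 0.00722 to 1.00 over all alternatives. By list, camera called 12 lists at its preset correlation and 0 with an estimated one (3 at an unadjusted p under 0.05; adjusted p of these 12 lists from 0.405 to 0.745), and 22 of 100 splits of the embryos called 12 or more; members leaned one way without passing one by one. At the preset correlation the medial minus dorsal difference was below 0 for 8 lists and above 0 for 4. It was below 0 for lists that rose less medially, G2/M genes (median -0.18, camera adjusted p = 6.11e-14), S-phase genes (-0.10, 0.000122) and histone genes (-0.13, 0.0116), and for lists whose medians were lower medially than dorsally, pan-neuronal genes (-0.13, 0.0116), interneuron genes (-0.32, 0.000247), Cajal-Retzius cell genes (-0.42, 0.000122), hem genes (-0.29, 0.000288) and choroid plexus genes (-0.76, 0.00455). It was above 0 for Hedgehog targets (median 0.17, 0.000138) and endothelial genes (0.16, 5.91e-07), and for pericyte (0.14, 0.00141) and microglia genes (0.25, 4.90e-05), whose medians fell less medially (-0.12 and -0.12) than dorsally (-0.29 and -0.32). Of these 12 lists only the Hedgehog targets held a member past the test over all genes, 1 of 13, which was Ccnd1 (2 higher and 1 lower adjusted over the list alone). Only the hem list held another adjusted over the list alone (1 of 28). The Hedgehog, G2/M, Cajal-Retzius and endothelial lists kept their calls without each library in turn, but the Cajal-Retzius list lost its call with male libraries alone, as did the S-phase, histone, hem and choroid plexus lists. The pan-neuronal list lost its call without 5 libraries (control dorsal 1, mutant dorsal 2 and 4, control medial 6 and mutant medial 3), the histone list without 6 (control dorsal 3 and 4, mutant dorsal 3, control medial 2 and 5 and mutant medial 3) and the choroid plexus list without 5 (mutant dorsal 3, control medial 2 and 4 and mutant medial 2 and 4). The S-phase list lost it without mutant dorsal 3 (0.773) or mutant medial 1 (0.117), the pericyte list without mutant dorsal 3 (0.116), the interneuron and microglia lists without mutant medial 3 (0.149 and 0.0698) and the hem list without mutant medial 2 (0.110). With each embryo as a fixed block, the G1 (0.0217), erythroid (0.0152) and mitochondrial lists (0.0369) passed too, within ranges over all alternatives of 0.00627 to 0.910, 0.0152 to 0.745 and 0.00484 to 0.883.

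Between the regions of control cortex (5 medial against 6 dorsal libraries), the comparison shows which genes mark each piece of tissue. Htra1, a secreted protease gene, was 3.90 ± 0.51 higher medially on the log2 scale (adjusted p = 7.02e-05), as were Wnt8b, a signal gene of the hem (2.72 ± 0.76), Lhx9 (2.62 ± 0.24) and Zic1 (2.41 ± 0.43). Mc4r (-2.34 ± 0.41) and Pou3f1 (-2.0 ± 0.34) were lower medially. Crym, Loxl1, Rbp4, Rmst, Bcan and Adamts19 completed the 10 largest medial excesses, and Hs3st3b1, Lrrtm3, Ntm, Ube2ql1, Sla, Btbd11 and Fam84a were among the 10 largest dorsal ones. Ccnd1 (-1.51 ± 0.14), Cdk6 (-0.75 ± 0.18) and Ptch1 (-0.34 ± 0.10, adjusted p = 0.0141) were lower medially. Ccnd2 (0.50 ± 0.09), Smo (0.54 ± 0.08), Hopx (1.36 ± 0.30), Pax6 (0.36 ± 0.08), Sox2 (0.54 ± 0.08) and Eomes (0.28 ± 0.08) were higher medially.

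By list, camera called 15 lists between the control regions at its preset correlation and 0 with an estimated one (2 at an unadjusted p under 0.05; adjusted p of these 15 from 0.377 to 0.591), and 9 of 100 splits called 15 or more. At the preset correlation hem genes were higher in medial control cortex, with 23 higher and 1 lower of 28 (23 and 2 adjusted over the list alone; adjusted p = 1.31e-08) in camera, as were Cajal-Retzius genes with 13 higher and 1 lower of 14 (13 and 1 adjusted over the list alone; adjusted p = 2.18e-05). Radial glia markers had 17 higher and 2 lower of 24 (17 and 3 adjusted over the list alone; adjusted p = 2.18e-05), intermediate progenitor markers 12 higher and 3 lower of 23 (13 and 4 adjusted over the list alone; adjusted p = 0.0121), and Notch genes 13 higher and 2 lower of 20 (13 and 2 adjusted over the list alone; adjusted p = 0.000986). G2/M genes had 44 higher of 51 (46 adjusted over the list alone; adjusted p = 1.30e-16), S-phase genes 34 higher of 43 (37 adjusted over the list alone; adjusted p = 4.52e-12), G1 genes 10 higher and 3 lower of 24 (13 and 3 adjusted over the list alone; adjusted p = 0.00928), and histone genes 14 higher of 23 (17 adjusted over the list alone; adjusted p = 2.55e-05). Choroid plexus genes had 5 higher of 11 (8 adjusted over the list alone; adjusted p = 0.00928) and Hedgehog pathway components 10 higher and 1 lower of 23 (11 and 3 adjusted over the list alone; adjusted p = 0.0484). Pan-neuronal genes were lower medially, with 1 higher and 17 lower of 24 (1 and 19 adjusted over the list alone; adjusted p = 2.14e-08), as were upper-layer genes, with 3 higher and 12 lower of 18 (3 and 13 adjusted over the list alone; adjusted p = 0.000232). The endothelial list, with 1 lower of 18 (1 adjusted over the list alone; adjusted p = 0.0484), and the pericyte list, with 1 higher and 3 lower of 11 (1 and 6 adjusted over the list alone; adjusted p = 0.0484), passed downward. With each embryo as a fixed block, the endothelial (0.0736) and pericyte lists (0.120) did not pass, and the interneuron (0.0206) and erythroid lists (0.00336) did. Over all alternatives these 4 ran from 0.0157 to 0.591, 0.0222 to 0.460, 0.0206 to 0.643 and 0.00336 to 0.460. The choroid plexus list lost its call without control medial 4 (0.0754) and the G1 list without control medial 5 (0.0503). The endothelial, pericyte and Hedgehog component lists lost theirs in 12, 11 and 9 of the 19 fits without 1 library. Limma called 4387 of 13520 genes, 2373 higher and 2014 lower medially, and 2773 did not overlap between the libraries, 20.5% where chance gives 0.433% if libraries exchange freely and at most 6.25% if they exchange only within embryos (highest of the 31 other such splits, 10.6%). Those 31 splits include the exchange of the regions in all 5 pairs, which keeps the regional difference, so 10.6% may not be a chance level. Dorsal and medial libraries of the same genotype and number deviated alike from their group means (r across genes from 0.549 to 0.795 in 9 pairs), and with the embryo as a random block 6614 genes passed.

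Between the regions of mutant cortex (4 medial against 4 dorsal libraries), the comparison shows which regional differences the mutants held. Ccnd1 (-0.13 ± 0.16, adjusted p = 0.634) and Cdk6 (-0.01 ± 0.21, adjusted p = 0.978), both lower in medial control cortex, did not pass here. Under at least 1 alternative Ccnd1 did pass limma (lowest adjusted p = 0.0383), and Cdk6 passed in none (lowest adjusted p = 0.795). Limma's direct test of the difference between the effects did not pass for Cdk6 in any alternative either (lowest adjusted p = 0.204). A loss of its regional difference is therefore not shown. Loxl1 (3.22 ± 0.41), Dct (2.87 ± 0.50), the matrix gene Bcan (2.48 ± 0.40) and Hopx (1.84 ± 0.35, adjusted p = 0.00372) were among the 10 largest medial excesses, with Crym, Rmst, Rbp4, Fbln7, Fzd9 and Lhx9. Mc4r (-2.36 ± 0.47), Npy, an interneuron peptide gene (-2.34 ± 0.45), and Lhx6, a transcription factor gene of interneurons (-1.78 ± 0.39), were among the largest dorsal ones, with Lrrtm3, Hs3st3b1, Tfap2d, Cux2, Ntm and the antisense gene Dlx6os1_1, whose value is uncertain because the use of strand in counting is not given in the sources used here. Hhip was lower medially (-0.78 ± 0.20, adjusted p = 0.0109). Smo (0.40 ± 0.10), Pax6 (0.48 ± 0.10) and Sox2 (0.58 ± 0.09) were higher. Gli3 (adjusted p = 0.186), Eomes (0.103) and Olig2 (0.0689) did not pass, but did with the embryo as a random block (0.0162, 0.0255 and 0.0120), within ranges over all alternatives of 0.00197 to 0.490, 0.0136 to 0.427 and 0.0120 to 0.343. Olig2 also passed without mutant dorsal 3, control medial 2 or control medial 5, and Eomes without mutant dorsal 3.

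By list, camera called 14 lists between the mutant regions at its preset correlation and 0 with an estimated one (4 at an unadjusted p under 0.05; adjusted p of these 14 from 0.293 to 0.638), and 7 of 35 splits called 14 or more. At the preset correlation pan-neuronal genes were lower in medial mutant cortex, with 21 lower of 24 (21 adjusted over the list alone; adjusted p = 1.16e-12) in camera, as were interneuron genes with 2 higher and 15 lower of 24 (2 and 16 adjusted over the list alone; adjusted p = 0.000208) and upper-layer genes with 3 higher and 11 lower of 18 (3 and 12 adjusted over the list alone; adjusted p = 0.00267). Radial glia markers were higher, with 15 higher of 24 (16 adjusted over the list alone; adjusted p = 1.22e-07), as were hem genes with 11 higher and 1 lower of 28 (14 and 1 adjusted over the list alone; adjusted p = 4.99e-06) and Notch genes with 9 higher and 2 lower of 20 (10 and 5 adjusted over the list alone; adjusted p = 0.00234). S-phase genes had 12 higher of 43 (17 adjusted over the list alone; adjusted p = 5.42e-08), G2/M genes 7 higher of 51 (16 adjusted over the list alone; adjusted p = 2.48e-08), intermediate progenitor markers 6 higher and 1 lower of 23 (7 and 1 adjusted over the list alone; adjusted p = 0.0132) and Cajal-Retzius genes 4 higher of 14 (4 adjusted over the list alone; adjusted p = 0.0133). G1 genes had 4 higher of 24 (5 adjusted over the list alone; adjusted p = 0.0465), meningeal genes 2 higher of 15 (2 adjusted over the list alone; adjusted p = 0.0364) and BMP targets 3 higher and 1 lower of 12 (5 and 1 adjusted over the list alone; adjusted p = 0.0465). The histone list passed upward (adjusted p = 0.00352) with 0 of 23 members past limma over all genes or over the list alone (3 higher at an unadjusted p under 0.05). The G1, meningeal and BMP lists passed neither after quantile normalization nor with each embryo as a fixed block (0.0648, 0.0756 and 0.0704), which let the Hedgehog component (0.0342) and erythroid lists (0.0430) pass. Over all alternatives these 5 ran from 0.0157 to 0.612, 0.00250 to 0.612, 0.0288 to 0.293, 0.0232 to 0.638 and 0.0430 to 0.647. The Cajal-Retzius list lost its call without mutant medial 1 (0.0757), the meningeal list without mutant dorsal 3, mutant medial 1 or mutant medial 3, the G1 list without 5 and the BMP list without 8 of the 19 libraries in turn. Limma called 2545 genes, 1085 higher and 1460 lower medially. A fit on the 8 mutant libraries alone called 0 (3538 at an unadjusted p under 0.05), and the embryo as a random block called 5283. The libraries did not overlap for 2050 genes, 15.2% where chance gives 2.86% if libraries exchange freely and at most 12.5% if they exchange only within embryos (highest of the 7 other such splits, 1.19%).

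The mutant effects of the 2 regions largely ran the same way. Of the genes past the test in both, 1067 rose and 3085 fell in both regions as deposited, and 1 gene moved in opposite directions. The excess of shared falls depends on the scaling. After median-ratio rescaling, limma called 2112 genes higher and 1921 lower dorsally, and 2183 higher and 2258 lower medially. Independent calls in the 2 regions would give 127 shared rises and 1125 shared falls as deposited, but dorsal and medial libraries share embryos. In 100 shuffles of genotype over the embryos, at most 2 genes rose and at most 1 fell in both. The shuffles remove the genotype effect from each region, so a low count there does not show how far the regions share that effect. The gene with opposite directions, Prokr1, named here after its values were seen, fell by 0.27 ± 0.10 dorsally and rose by 0.46 ± 0.10 medially. Its dorsal call was lost after quantile normalization, after median-ratio rescaling, with embryo sex as a covariate and in 7 of the 19 fits without 1 library (control dorsal 2, 3, 4 and 5 and mutant dorsal 1, 2 and 4; adjusted p up to 0.115), with adjusted p over all alternatives from 0.00132 to 0.789, so its opposite directions rest on a weak call. At least 2-fold in both were 58 rises and 31 falls. Across the 13520 genes the log2 changes of the 2 regions had Pearson's r of 0.873 and a covariance of 0.110; genes are not independent replicates. In the same shuffles r ran from 0.407 to 0.855 with a median of 0.679, and the covariance reached at most 0.0773. The differences between regions were likewise shared by the genotypes: 976 genes were higher and 1239 lower medially in both control and mutant cortex, where independent calls would give 190 and 217, and 1 gene went in opposite directions. That gene, Lypd1, also named after its values were seen, was lower medially in controls (-0.44 ± 0.15) and higher in mutants (0.70 ± 0.17). Its control call was lost at a pseudocount of 5, without a filter, with male libraries alone and in 5 of the 19 fits without 1 library (control dorsal 2, 4 and 6 and control medial 3 and 6; adjusted p up to 0.0733), with adjusted p over all alternatives from 0.00127 to 0.949, the highest within split A with its 1 medial control library.

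**Figure D3:**
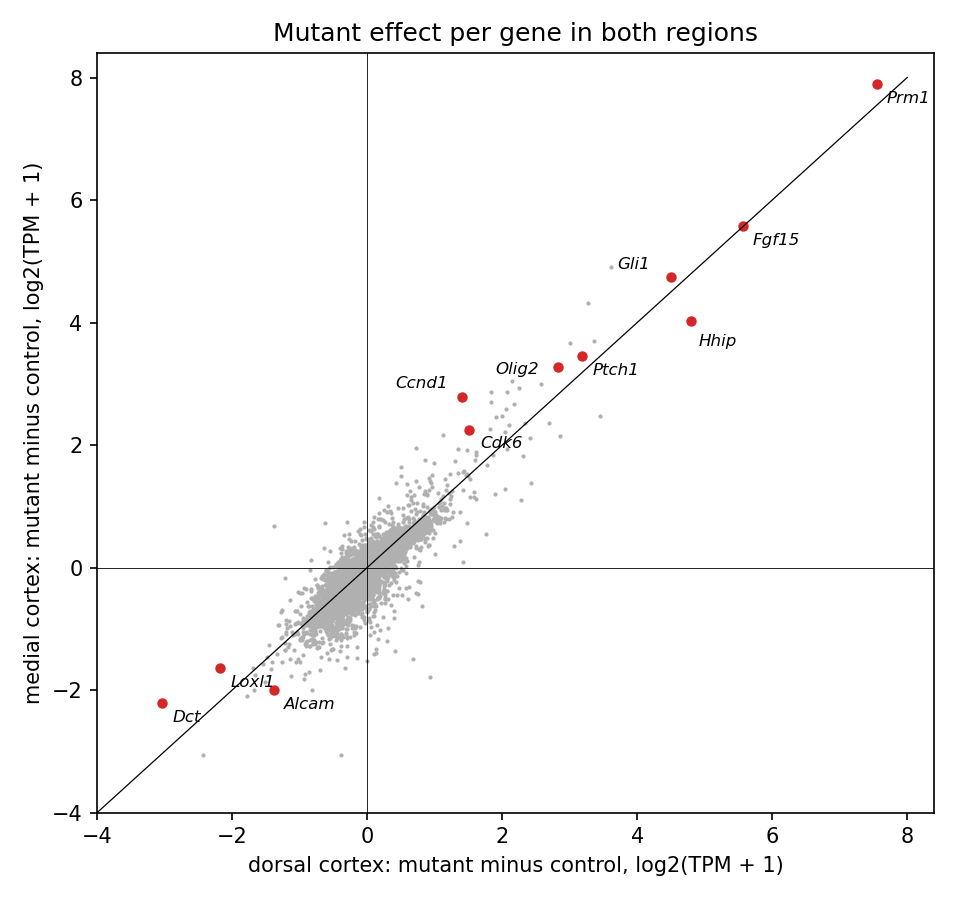
Mutant minus control change in log2(TPM + 1) per gene in dorsal (horizontal axis) and medial cortex (vertical axis) for the 13520 tested genes (points), with named genes in red and the line of equal change in black. Pearson's r across genes is 0.873.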

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

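The rules for values that stand apart and for differences between regions were fixed before the data were examined; only the look at which embryos made up the highest split and the tests of splits with each embryo as a block came after.

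The mutant effect on Ccnd1 was 1.38 larger in medial than in dorsal cortex on the log2 scale (limma, adjusted p = 0.0464), with all 4 mutant medial libraries above all 5 control medial libraries and all 4 mutant dorsal above all 6 control dorsal libraries. It was called in 15 of 37 alternatives, and leaving out 1 library lost the call 17 times of 19. Of 100 splits of the embryos, 3 called 1 gene or more, the real one included. These splits put the genotype effect into the spread within groups, which can hold their calls down, so they do not exclude chance. The highest other split called 26 genes. That split set control embryos 2, 3 and 6 and mutant embryo 1 against the others. The 8 other drawn splits without an embryo of split A (control embryos 1 and 5 and mutant embryos 3 and 4) on that side called fewer genes. Whether the 26 genes reflect a structure among the embryos was not tested. With each embryo as a fixed block, which keeps the genotype effect out of the spread, 2 of the 126 splits of the 9 embryos with both regions called as many as the real 16 genes, the other one 130. By an unadjusted p under 0.05, 21 of 126 called as many as the real 1201 genes, so chance stays open for the number of genes. For Ccnd1 itself, 2 of the 126 splits, the real one included, gave a p as small (limma, unadjusted p = 3.60e-05). Ccnd1 was singled out in these same data as the only gene called in the main fit, so that count does not exclude chance for it. By list, camera put the medial minus dorsal difference above 0 for Hedgehog target genes, a list that holds Ccnd1 (adjusted p = 0.000138), and for endothelial cell (5.91e-07), pericyte (0.00141) and microglia genes (4.90e-05). It put it below 0, a lower median change medially, for G2/M (6.11e-14), S-phase (0.000122), histone (0.0116), pan-neuronal (0.0116), interneuron (0.000247), Cajal-Retzius cell (0.000122), cortical hem (0.000288) and choroid plexus genes (0.00455). As many lists, 12 or more, were called in 22 of 100 splits (highest other 18), so chance cannot be excluded for the number of lists, and none of the 12 passed with an estimated correlation (lowest adjusted p = 0.405). List by list, an adjusted p as small as the real one came up in 1 of 100 splits, the real one, for the Hedgehog target and G2/M lists and in 12 to 38 for the other 10. These are the same splits, with the genotype effect in their spread, so the low counts of the Hedgehog target and G2/M lists do not exclude chance either.

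Within each group, a library was set apart where its log2(TPM + 1) lay far from the others for a named gene, relative to the range of the group. This was so for 18 values in 334 groups of values, and chance alone sets about 1 in 20 groups apart. In mutant medial library 1, the values set apart were Wnt8b 23.7 TPM (others 0.0765 to 0.598), Gli2 4.80 TPM (others 7.41 to 7.76), Eomes 255 TPM (others 296 to 304) and Ddx3y 68.2 TPM (others 78.4 to 80.3). In mutant medial library 2 they were Dio3 11.1 TPM (others 3.20 to 3.70) and Apln 16.8 TPM (others 12.5 to 13.0). In mutant medial library 3 they were Etv5 4.99 TPM (others 12.7 to 14.6), Gap43 173 TPM (others 203 to 207) and Sox1 113 TPM (others 89.4 to 92.8), and in mutant medial library 4 Prokr1 7.81 TPM (others 9.13 to 9.37). Control medial library 5 stood apart with Ccnd1 29.6 TPM (others 13.9 to 15.7), Gli3 34.5 TPM (others 25.8 to 26.4) and Sstr1 3.77 TPM (others 6.66 to 7.41). Control dorsal library 1 did so with Prokr1 7.82 TPM (others 10.6 to 12.5) and Rmst 6.81 TPM (others 3.79 to 4.70). Mutant dorsal library 2 had Dmrt3 1.67 TPM (others 4.34 to 4.53), and mutant dorsal library 3 had Cdon 113 TPM (others 85.1 to 88.8) and Sp8 5.24 TPM (others 4.21 to 4.37).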

How the results depend on the processing

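The alternatives with embryo sex, male libraries alone, the split of the embryos, or each embryo as a fixed block were tests chosen after the data were seen, as was leaving out libraries for the gene lists; the others were chosen before. The counts of genes lay within 1.5 times the reported ones under both pseudocounts, the 5 TPM filter, quantile normalization, median-ratio rescaling, rescaling without the highest genes, array weights, the title number as a block over all 19 libraries and embryo sex as a covariate. Over these the dorsal count ran from 4033 to 5218 and the medial one from 4439 to 5781. No filter and moderation without trend and robust settings left 0 genes in the difference between regions in limma (839 and 463 at an unadjusted p under 0.05; the cause was not tested), and moved the other counts by less than 1.5 times. A fit on the libraries of the comparison alone called 0 genes between mutant regions (3538 at an unadjusted p under 0.05; the cause was not tested) and moved the others by less than 1.5 times. The replicate block with the embryo as a random block gave 49 genes for the difference between regions, 6614 between control regions and 5283 between mutant regions. Each embryo as a fixed block gave 16 (Ccnd1 and Cdkn1c among them), 6325 and 4950; its construction leaves no comparison of genotypes within a region. The title number as a block on the libraries with a partner gave 6091 and 4201. These blocks remove the spread between embryos from comparisons within an embryo. Among the genes named in the text, the random block added calls for the difference between regions (Adamts19, Cacng5, Cdkn1c, Lypd1, Moxd1, Prokr1, Prph and Sox1), dorsally (Reln), medially (Crym and Gsx2, while Zic1 lost its call), between control regions (Dusp26, Gap43, Hs3st1 and Jag1) and between mutant regions (Apln, Cdkn1c, Dio3, Eomes, Gli3, Gsx2, Nxph4, Olig2, Prph and Unc5d). The title number does not pair controls with mutants, so a block by number over all libraries joins control and mutant embryos that are not matched. The title number as a block over all libraries ended the list calls of ventral progenitors medially, of Hedgehog components, endothelial and pericyte genes between control regions and of G1, meningeal and BMP genes between mutant regions. It added those of sex-linked genes in both regions, hem genes medially, upper-layer genes for the difference between regions, and interneuron and erythroid genes between control regions. Male libraries alone, which leave 3 control dorsal and 2 control medial libraries, gave 2892 genes dorsally, 3085 medially, 0 for the difference between regions (124 at an unadjusted p under 0.05), 11 between control and 1633 between mutant regions. There the choroid plexus list reversed its direction in the difference between regions (adjusted p = 0.859, against 0.00455; the cause was not tested). The S-phase (0.0939), Cajal-Retzius (0.0614), hem (0.794) and histone lists (0.177) lost their calls for that difference, and the radial glia (0.0483) and mitochondrial lists (0.0151) gained them. Male libraries alone also ended the list calls of choroid plexus and endothelial genes between control regions and of G1 and BMP genes between mutant regions, and added those of oligodendrocyte precursor genes dorsally and of lateral and dorsal pallium genes medially; embryo sex as a covariate added the last alone. With the embryo split as a covariate 0 genes passed for the difference between regions (643 at an unadjusted p under 0.05; the cause was not tested). Within split A (control embryos 1 and 5 and mutant embryos 3 and 4), 7 libraries, limma called 1538 genes dorsally, 69 medially and 0 for the difference between regions (153 at an unadjusted p under 0.05), between control regions (1220) and between mutant regions (1850), and within split B, 12 libraries, 2964 dorsally, 2 for the difference and 1322 between mutant regions. Fewer libraries are tested in both. In split A the medial controls are library 5 alone, so its medial, difference and control region counts say nothing about stability; nor do the reversed signs of Cpxm2 and Entpd2 between control regions there (-0.00116 and -0.10). With an estimated correlation, camera called 5 lists dorsally and 0 medially, for the difference between regions, between control and between mutant regions (7, 3, 2 and 4 at an unadjusted p under 0.05); the estimate widens the test for lists whose members vary together. Quantile normalization gave 9, 11, 14, 14 and 11 lists, with FGF and mitochondrial genes added for the difference between regions and Hedgehog components lost between control regions. Of the 19 fits without 1 library, 7 also called the FGF list and 5 the mitochondrial list for that difference. The adjusted p of the FGF list in camera ran from 0.00663 to 0.647 over all alternatives. The correlation of 0.873 between the mutant effects of both regions was 0.836 at a pseudocount of 0.1, 0.902 at 5, 0.848 without a filter and 0.910 at 5 TPM; how genes of low TPM enter differs between these settings, and the cause was not tested. Leaving out 1 library gave 3861 to 5181 genes dorsally, 4563 to 5493 medially, 3355 to 4547 between control regions and 7 to 8, 9 to 12, 9 to 17, 12 to 17 and 12 to 16 lists in the 5 comparisons. For the difference between regions it gave 0 to 3 genes: 3 without control dorsal 1, 2 without control medial 5 and 0 without any of the others (348 to 613 at an unadjusted p under 0.05 in limma). Between mutant regions it gave 1136 (without mutant dorsal 2) to 3673 (without mutant dorsal 3), with 1371 without mutant dorsal 4 and 1309 without mutant medial 3. The correlation ran from 0.828 (without mutant dorsal 3) to 0.886 (without control medial 2). Of the named genes called dorsally, 34 of 61 kept the call in each alternative, of those called medially 19 of 66, of those called between control regions 2 of 61, between mutant regions 2 of 49, and for the difference between regions 0 of 1 (15 of 37 alternatives kept it). Of the lists, 5 of the 7 called dorsally did, and 0 of the 10 called medially, of the 12 for the difference, of the 15 between control and of the 14 between mutant regions; each list of these 4 comparisons lost its call with an estimated correlation. Depth is unknown, so no limit from depth can be given.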

Other observations

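Chosen only after the result was seen were the tests of the transgene as a source of Prm1, of sex, copies and genetic background behind the split of the embryos, and of histones and sex behind the asymmetry. The tests of spermatid genes, of the ROSA26 region and of other splits into groups of the same sizes were written before. The splits that part each embryo's pair of libraries were not, since the pairing comes from the data.

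Ccnd1 and Cdk6 differed between the regions in controls and did not pass between the regions in mutants, though Ccnd1 did so under at least 1 alternative (limma, lowest adjusted p = 0.0383). For Cdk6, limma's direct test of the difference between the effects passed neither in the main fit nor in any alternative (lowest adjusted p = 0.204). A loss of its regional difference in the mutants is therefore not shown. Ccnd1 stood at 50.1 TPM in dorsal and 17.7 TPM in medial controls but at 135 and 123 TPM in the mutants. The difference between the effects was 1.58 (log2) without control medial library 5, which stood apart for Ccnd1, and 1.09 with male libraries alone; the 0.81 within split A rests on that library as the only medial control. A common level of Ccnd1 in responding cells, a larger response of medial cells and a larger share of responding cells in medial tissue would give the same values, and none was tested. Prokr1, whose mutant effect went opposite ways in the regions, and Lypd1, whose regional difference went opposite ways in the genotypes, were singled out after their values were seen, and 1 of the 2 calls behind each was lost in several alternatives. With each embryo as a fixed block, both were among the 16 genes whose mutant effect differed between regions (Prokr1 0.81 ± 0.09 and Lypd1 1.25 ± 0.16).

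S-phase, G2/M and histone lists rose in both regions while, as deposited, radial glia, outer radial glia and intermediate progenitor lists moved both ways. With an estimated correlation the first 3 passed camera dorsally (adjusted p = 0.0401 each) and not medially (0.0847 each). More cycling cells and more transcripts per cycling cell raise such lists alike, and bulk libraries do not separate them. In 59 of 100 splits of the dorsal libraries camera called 7 or more lists (highest other 10), and in 62 of 100 medially 10 or more (highest other 20), so chance cannot be excluded for the number of lists in either. It can be excluded for the number of genes: 1 of 100 splits, the real one, called as many as 5070 dorsally (highest other 1268) and 1 of 100 as many as 5357 medially (highest other 3153). Between control regions 1 of 100 splits called as many as 4387 genes (highest other 3312), and 9 of 100 as many as 15 lists (highest other 17), so chance cannot be excluded for the lists. Between mutant regions 1 of 35 splits called as many as 2545 genes (highest other 2081) and 7 of 35 as many as 14 lists (highest other 18), so chance cannot be excluded for the lists. These splits ignore that libraries pair by embryo. Among splits that part each embryo's pair of libraries, 1 of 32 called as many genes between control regions (highest other 3312). Another of these 32 exchanges the regions in all 5 pairs and so keeps the regional difference. It is not independent of the real split, so these splits give no clear verdict on chance for the genes. Between mutant regions there are 8 such splits, too few for a share under 0.05, with 2545 genes in the real one and 0 in the highest other. List by list, an adjusted p as small as the real one came up dorsally in 1 of 100 splits for the Hedgehog target and the 4 cell cycle and histone lists, in 2 for the ventral and in 6 for the deep-layer list. Medially it did in 1 for the Hedgehog target, S-phase and G2/M lists, in 2 for G1, in 5 for histones and in 12 to 42 for the others. Between control regions it did in 1 for radial glia and Notch genes and in 3 to 34 for the others, and between mutant regions in 1 of 35 for pan-neuronal, radial glia and Notch genes and in 4 to 14 for the others. Dorsally, the lowest adjusted camera p of another split lay near the real one for G1 genes (1.75e-10 against 1.17e-10) and histones (1.93e-25 against 7.76e-27). It was 1.04e-38 for S-phase genes (real 3.60e-52), 1.83e-37 for G2/M genes (real 1.00e-46) and 0.123 for Hedgehog targets (real 0.00836). The small size of such p-values alone therefore does not speak against chance.

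Prm1 lay between 132 and 540 TPM in the 8 mutant libraries and at most at 0.603 TPM in the 11 control libraries. A program of spermatid genes is argued against, since the highest value of Prm2, Prm3, Tnp1 and Tnp2 in any mutant library was 0.0945 TPM. Prm1 sequence carried by the Cre transgene, for example in its polyadenylation signal, may account for the reads. The lowest mutant value of 132 TPM has the form this needs, but genotype and transgene coincide here and the reads were not examined, so transgene and endogenous Prm1 cannot be told apart. No other biological explanation was tested.

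Within groups, the libraries fell into 2 sets along 1 axis that took 35.9% of the variance of the deviations: control embryos 1 and 5 and mutant embryos 3 and 4 against the others. On the side of the female libraries fell 6 male ones, those of control embryo 6 and mutant embryos 1 and 2. The mutant groups are all male and centred on their own means, so their sides cannot test sex. Among controls, male embryo 6 fell on the female side (17.45 dorsally and 8.56 medially along the axis), and male embryos 1 and 5 on the other. Ddx3y and Xist were among the 100 genes with the largest weight. Sex may thus take part, and this test does not decide on it. The 100 genes with the largest weight held 27 annotated pseudogenes, where random sets of tested genes held 1 (median) and 3 (highest 95%), so reads shared between near-identical copies may take part. A first test of genetic background counted 25 neighbouring pairs within 1 Mb among those genes (random median 8, highest 95% 12), but they include tandem copies, pseudogenes and Y-linked genes. It was replaced by one on autosomal protein-coding genes, which counted 12 pairs (random median 8, highest 95% 13) and leaves strain differences between embryos open, as does the design, which gives no batch, litter or strain. Among the 100 such genes with the largest weight were the hem list members Dkk3, Wnt8b, Rspo2, Rspo1, Wnt3a and Lmx1a. Their weights shared 1 sign (0.0226 to 0.0352), as did that of the choroid plexus gene Ttr (0.0222). The embryos thus also differed along this axis in genes of medial tissue, and the cause was not tested.

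Of the genes called in the mutants, more were lower than higher as deposited: 25.1% of the calls of both regions were higher, and the median gene changed by -0.10 dorsally and -0.11 medially. TPM sum to a fixed total, so rising histone transcripts may push down the others. Rescaled without 71 histone genes, the median was -0.03 dorsally and -0.0463 medially, 42.4% of calls were higher, and 4047 and 4478 genes passed. The bound of -0.05 was set after a first test by median-ratio rescaling (50.7% higher) was dropped because it centres the median by construction, the medial value lies close to that bound, and part of the shift stays open. Sex is argued against as the source of the calls, since with sex in the fit 4612 genes passed in the comparison with fewer calls; a true excess of lowered genes was not tested apart from this.

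SmoM2 is carried at the ROSA26 locus in mouse lines in common use, which may bring linked strain sequence. Of 92 tested genes within 10 Mb of ROSA26 on chromosome 6, 32.6% changed the same way in both regions, against 30.9% of all tested genes and 40.2% in the highest 95% of 1000 windows, so an excess near the locus was not seen. Ttr, a choroid plexus gene, stood at 934 TPM in control medial library 4 and 161 TPM in mutant medial library 3. Col1a1, a meningeal gene, stood at 13.3 TPM in mutant medial library 3.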
